A study of Caenorhabditis elegans with 4 samples.

How the data were processed

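Chromatin immunoprecipitation followed by sequencing (ChIP-seq) was carried out on starved first-stage (L1) larvae of the nematode Caenorhabditis elegans. The hermaphrodites carried a transgene that expresses LSY-2 fused to GFP and short epitope tags, together with a rescuing copy of unc-119. Per the labels' protocols, animals were fixed with 2% formaldehyde, chromatin was sonicated, and protein-bound DNA was collected with anti-GFP antibodies. A part of each extract was kept as input, the total DNA control. The 4 samples are 2 immunoprecipitated libraries (ChIP replicates 1 and 2) and 2 input libraries with the same replicate numbers. The labels do not say whether the replicates came from separate cultures, so their spread may be technical.

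The authors deposited 3 peak lists, 1 for each ChIP library and 1 combined list. Per the file headers, positions are on the WormBase WS220 genome build, and the source column of each row names the SPP peak caller and the irreproducible discovery rate (IDR), a method that keeps peaks ranked alike in both replicates. The aligner, the versions, the thresholds, the way input was used and the way the combined list was made are not given in the sources used here. The value attached to each peak in the deposited lists is a score whose scale is not stated. Many peaks share the highest score of their list, so the score was used only to rank peaks within a list, with ties ordered by the peak number that the authors gave. Read counts are not given, so the depth of each library is unknown and no signal was compared across lists. No values of the input libraries were analysed here, and ChIP was therefore not compared with input.

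Overlap between lists was counted at a minimum of 1 bp. For chance overlap, 1 list was rotated by a random distance along each chromosome, which keeps widths and spacing, 1000 times (100 times for the setting that asks for 50% of the shorter peak). Rotation moves dense regions along with the rest, so it does not account for regional density that the lists share. P-values are one-sided permutation p-values, and 0.001 is the smallest that 1000 rotations can give. Ranks were compared by Spearman's rho over pairs of peaks that were each other's best ranked overlap. For density, each chromosome was taken to run from its first base to the last peak end in any list. Peaks were assigned by midpoint to full blocks of 100 kb, and each chromosome was cut into 3 equal parts, the outer 2 called arms and the middle one centre. X was compared with the autosomes by permuting blocks over the genome, and arms with centres by permuting blocks within chromosomes. Each test used 10000 permutations and was two-sided, so that 0.0001 is the smallest p possible. Centre over arm ratios have 95% percentile intervals from 10000 block bootstraps. Replicate differences per chromosome were tested with an exact two-sided sign test over 1 Mb blocks. Benjamini-Hochberg adjustment was made over the 6 nuclear chromosomes. Shares have 95% Wilson intervals, or exact Clopper-Pearson intervals for the combined list against the replicates, which cover counting error only. For a share of 0, the share that 3 counts of the total would give is also stated. The tests treat blocks or peaks of the lists as units and not animals.

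The functions were tested on simulated lists. Of 29979 replicate 1 peaks, 60.3% were kept in place apart from a shift shorter than any peak. All kept peaks (100%) were found again, which so short a shift made certain, and the overlap count equalled that of bedtools. The overlap was 70.8% of all peaks, above the kept share, since some peaks that were not kept still had an overlap. The overlap shares given below likewise include overlaps by chance. Of 50 lists with uniform density, 0 gave p under 0.05 for X against autosomes and 3 did so for arms against centres. The uniform lists had no clustering of peaks, so they do not show the error rate of these tests on clustered lists. All 20 lists with X density thinned to 0.7 were called lower on X. The work used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, statsmodels 0.14.6, matplotlib 3.10.9 and bedtools 2.31.1.

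The lists carry no gene names. The gene table used for names is on another assembly than WS220, and coordinates of different builds were not mixed. Comparisons of peaks with genes, gene groups, gene types, base composition and the transgene's own loci had been planned and were not made, and the rule for naming genes was applied to regions instead: the 20 best ranked combined peaks are named by position. The 3 best ranked peaks absent from the other replicate, the densest 40 kb window and the longest peak-free interval were chosen after their values were seen. Alternatives covered the overlap rule, the score threshold, the matching of peaks, the block length, the measure of density, the merging of overlapping peaks, the ranking by peak number and leaving out each replicate. For the last of these, the combined list was replaced by the 9712 best ranked peaks of the other replicate.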

Results

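LSY-2 is a zinc finger transcription factor known for its part in the left-right asymmetry of the ASE taste neurons of Caenorhabditis elegans. The series mapped where a GFP-tagged LSY-2 bound the genome in whole L1 larvae that had been starved, a state in which the larva arrests its development. Each of the 2 ChIP libraries had a list of 30000 peaks, and a combined list held 9712 peaks. All positions are 1-based on WormBase WS220. Since both replicate lists stop at 30000 peaks, their length is not a measure of binding, and the read depth behind them is unknown.

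The first comparison described the regions that the authors called as peaks in the immunoprecipitated DNA. The combined peaks covered 3.43% of the nuclear genome and fell into 9276 separate regions once overlapping peaks were merged. The best ranked region was on chromosome IV from 13788553 to 13789065, and it ranked 8 in replicate 1 and 4 in replicate 2. The next was on chromosome II from 10868636 to 10869183, with ranks 2 and 10. Another lay on chromosome V from 15511525 to 15512086, with ranks 35 and 1, and a further one on chromosome IV from 1094093 to 1094682, with ranks 3 and 9. All 20 best ranked combined regions were within the first 100 peaks of both replicates. Their lowest standing was rank 75 in replicate 1 and rank 70 in replicate 2. These ranks describe the combined list and do not test agreement, since IDR, where used, keeps peaks ranked alike in both replicates.

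Chromosome III held 4 of these 20 regions, at 5442725 to 5443275, 8085195 to 8085725, 4019770 to 4020287 and 2780703 to 2781248. Chromosome I also held 4, at 13434239 to 13434789, 9625814 to 9626307, 6220718 to 6221276 and 10622638 to 10623157. Besides the region already given, chromosome II held 8884149 to 8884694, the best ranked peak of replicate 1 and peak 49 of replicate 2. It also held 8124740 to 8125303, 8569197 to 8569731 and 3076857 to 3077394. The remaining ones were 12371768 to 12372315, 4749776 to 4750316 and 11566082 to 11566579 on chromosome IV, and 12318055 to 12318597 on chromosome V. X held 0 of the 20, with a 95% Wilson upper limit of 16% (15% at 3 counts of the total). These 20 regions had a median width of 544.5 bp and a range of 494 to 590 bp, but the median was 320 bp in the best ranked 20% of the combined list, 245 bp in the next 20% and 416 bp in each later 20%. Over the whole combined list peaks measured 365 ± 103 bp (SD, n = 9712 peaks), and 61.4% of them had a width of exactly 416 bp. In the replicate lists the commonest width was 420 bp in replicate 1, for 91.9% of peaks, and 410 bp in replicate 2, for 90.3%. A highest score was shared by 36.1% of combined peaks, 19.4% of replicate 1 peaks and 5.58% of replicate 2 peaks, and the order among those peaks comes from their numbering.

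The second comparison asked how far the replicates marked the same regions. Of the 30000 replicate 1 peaks, 70.1% (95% interval 69.6 to 70.7) overlapped a replicate 2 peak, and 69.9% (69.3 to 70.4) of replicate 2 peaks overlapped a replicate 1 peak. Rotating a list along the chromosomes gave 21.6% on average in both directions and at most 25.1% (permutation p = 0.001, one-sided, the smallest possible). The strongest regions were nearly all shared. Among the 3000 best ranked peaks, 99.5% of replicate 1 peaks and 96.9% of replicate 2 peaks had a partner in the other list. The share fell to 43.9% and 46.5% in the last 3000, which was still above the highest rotated values of 25.4% and 25.7%. Rotation also parts dense regions that both lists share, and shared regional density can by itself raise overlap above the rotated values. The excess in the last 3000 therefore does not show that weak peaks mark the same sites. The lists hold only 1 interval in common with the same start and end, so the replicate lists are not copies of 1 another.

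**Figure D1:**
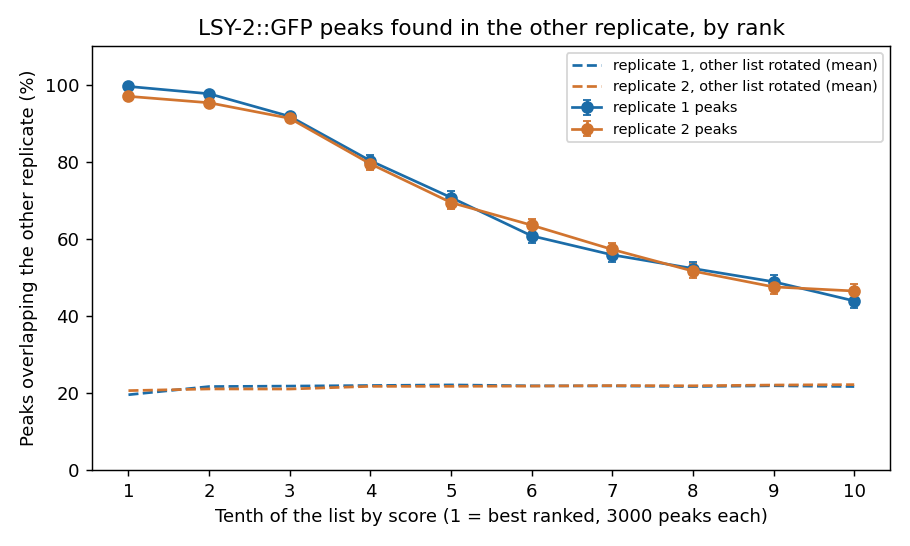
The share of peaks that overlap the other replicate (%, vertical axis) is plotted for successive groups of 3000 peaks in order of score, with points for each replicate, 95% Wilson bars for counting error and dashed lines for the mean after rotation. Replicate 1 falls from 99.5% to 43.9% and replicate 2 from 96.9% to 46.5%, both above about 22% after rotation.

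Peak order was then compared between the replicates. Of the 100 best ranked peaks of each replicate, 79 overlapped the first 100 of the other, and of the 20 best ranked, 7 did. Spearman's rho of the scores was 0.74 across 17264 one-to-one pairs, where peaks are not independent replicates. The rho was 0.59 in the better 50% of each list by score and 0.88 in the better 50% when peaks were ordered by their number. Within the first 3000, 63.9% of replicate 1 peaks were also among the first 3000 of replicate 2 by score, and 87.5% by peak number.

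A few peaks near the front of 1 list had no counterpart in the other. Of the first 3000 peaks, 15 of replicate 1 and 92 of replicate 2 had no counterpart anywhere in the other list, and 45 of replicate 2 had none when peaks were ordered by number. The best ranked of these in replicate 1 were on chromosome II from 7301692 to 7301942 (rank 898), on V from 9930687 to 9930897 (rank 1613) and on IV from 9884352 to 9884477 (rank 1833). In replicate 2 they were on chromosome II from 4999193 to 4999473 (rank 486), on II from 13908577 to 13908841 (rank 542) and on I from 5164903 to 5165148 (rank 805). All 6 were absent from the combined list, although 1 of the 15 and 24 of the 92 overlapped a combined peak.

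A further comparison set the combined list against each replicate. It describes the list and does not test agreement, since IDR, where used, keeps peaks ranked alike in both replicates. Of the combined peaks, 98.9% (exact 95% interval 98.7 to 99.1) overlapped a replicate 1 peak, 99.7% (99.5 to 99.8) a replicate 2 peak and 98.6% (98.4 to 98.8) both. Replicate 1 alone held 31 of them and replicate 2 alone held 103. None of the 9712 lay outside both lists, with an exact 95% upper limit of 0.0380% (0.0309% at 3 counts of the total). Against the 9712 best ranked peaks of each replicate, 77.2% overlapped both. In the other direction, 98.2% of the nuclear replicate 1 peaks that were among the first 9712 of both replicates were in the combined list, and 98.1% for replicate 2. Of those among the first 9712 of their own replicate alone, 45.6% of replicate 1 peaks and 53.7% of replicate 2 peaks were in it. The start and end of 1 combined interval matched a replicate 1 interval and those of 0 matched a replicate 2 interval.

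The last comparison described where on the chromosomes the regions lay. Chromosome III was the most densely bound, with 140 combined peaks per Mb, followed by I with 119.9 and II with 104.4. Chromosome IV had 84.7, X had 82.9 and V had 68.2. Taking the 9712 best ranked peaks of each replicate, the densities were 138 ± 2.98 per Mb on III, 119.5 ± 2.11 on I, 104.6 ± 1.11 on II, 86.2 ± 2.30 on IV, 82.6 ± 6.23 on X and 68.05 ± 1.05 on V (SD, n = 2 replicates). The gaps between III, I, II and V were larger than this spread, and the difference between IV and X was not. By permutation of 100 kb blocks against the other chromosomes, III and I were denser (adjusted p = 0.0002 each), V (adjusted p = 0.0002), X (adjusted p = 0.0024) and IV (adjusted p = 0.010) were sparser, and II did not differ by this test (adjusted p = 0.15).

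**Figure D2:**
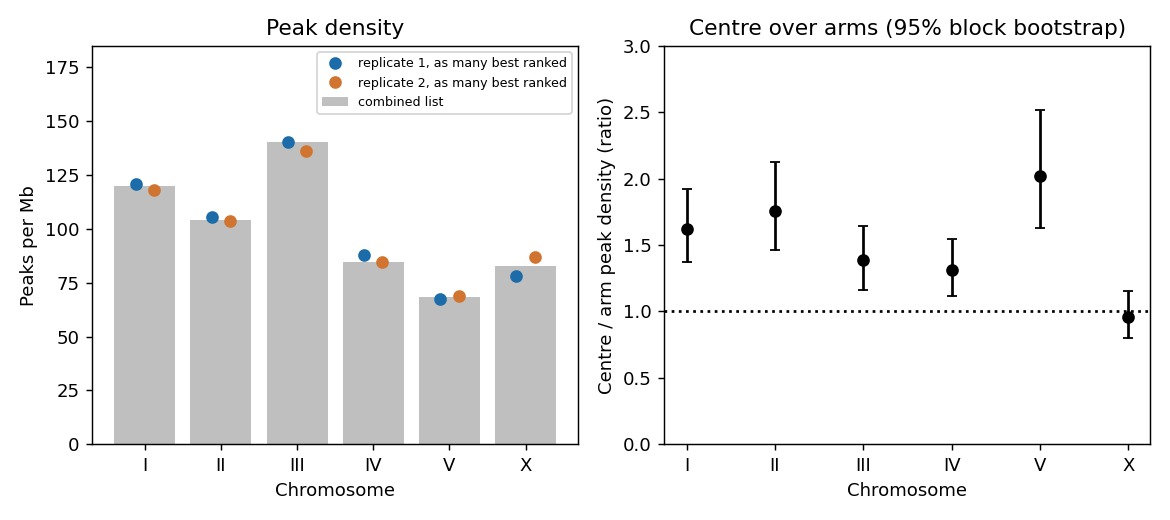
Left, combined peaks per Mb for each chromosome (bars) with the 9712 best ranked peaks of each replicate (points); right, the ratio of peak density in the centre to that in the arms (points) with 95% block bootstrap intervals, and 1 marked by a dotted line. III is highest at 140 and V lowest at 68.2 peaks per Mb, and X is the chromosome whose interval includes 1.

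Centres were more densely bound than arms. Over all chromosomes, arms had 8.35 ± 5.91 peaks per 100 kb (SD, n = 665 blocks) and centres 12.4 ± 7.11 (n = 334 blocks; permutation p = 0.0001, two-sided, the smallest possible). The centre over arm ratio was 2.02 on V (95% interval 1.63 to 2.51), 1.76 on II (1.46 to 2.12), 1.62 on I (1.37 to 1.92), 1.39 on III (1.16 to 1.64) and 1.31 on IV (1.12 to 1.55). On X it was 0.96 (0.80 to 1.16). The geometric mean of the autosome ratios was 1.66 times that of X (95% block bootstrap interval 1.37 to 2.04), and this interval left out 1. The interval reflects the sampling of blocks and not the spread between chromosomes, and X is 1 chromosome. With 500 kb blocks, the contrast on IV no longer passed (ratio 1.25, block permutation, adjusted p = 0.081), and the contrasts on the other autosomes did.

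**Figure D3:**
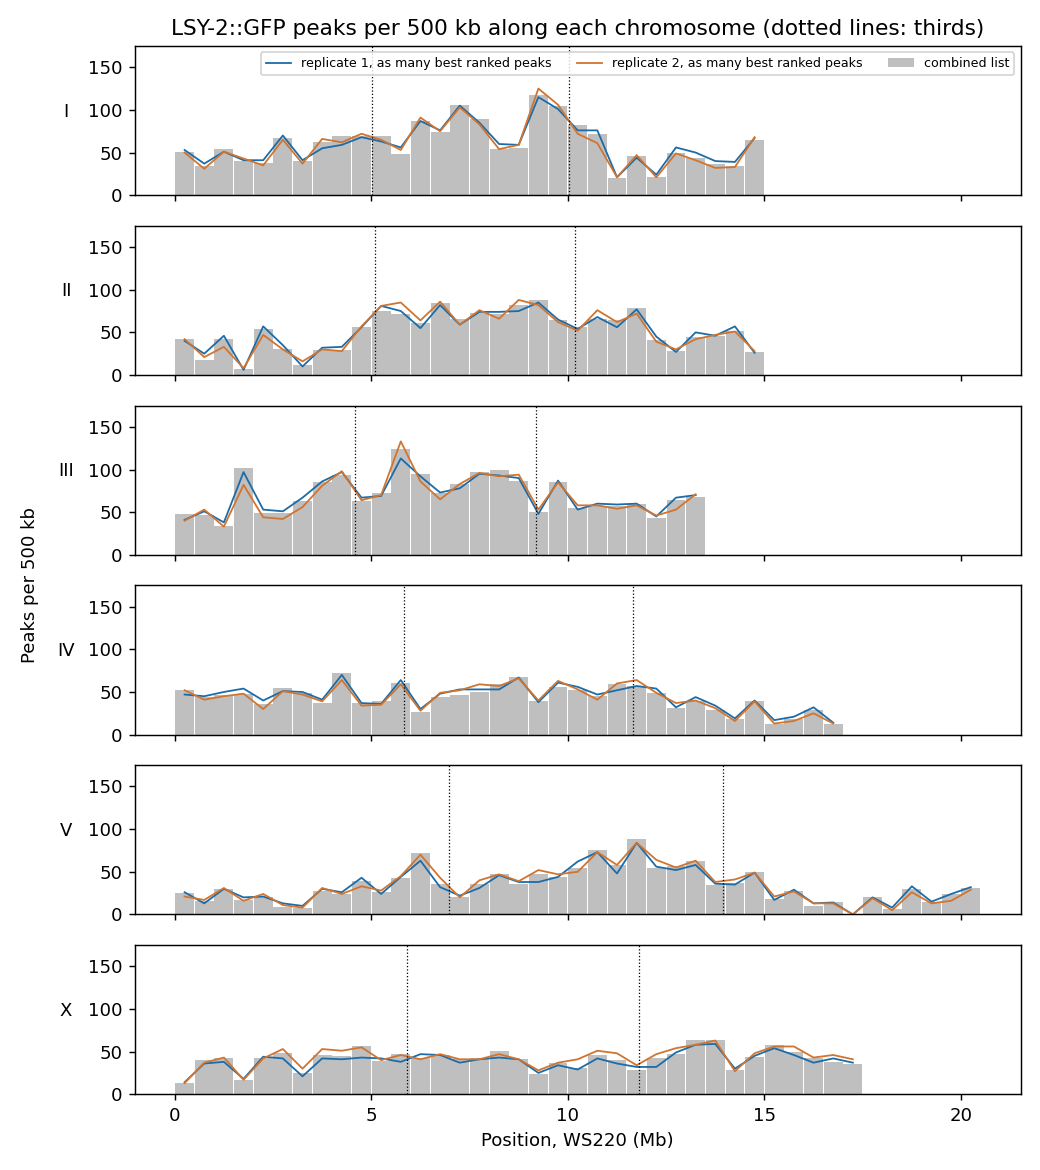
Peaks per 500 kb (vertical axis) are drawn against WS220 position in Mb for each nuclear chromosome, with bars for the combined list, lines for the 9712 best ranked peaks of each replicate and dotted lines where arms meet centre. The autosomes rise towards their centre, most on V (ratio 2.02), while X stays level (ratio 0.96).

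X held a smaller share of the peaks that stood first in the lists than of the longer lists. Combined peaks were sparser on X (8.30 ± 5.17 per 100 kb, n = 177 blocks) than on the autosomes (9.99 ± 6.84, n = 822 blocks; permutation p = 0.0025, two-sided). With 500 kb blocks the difference was -1.76 per 100 kb, nearer the threshold (block permutation p = 0.034). It was -1.18 without replicate 1 (permutation p = 0.027) and -2.24 without replicate 2 (permutation p = 0.0002). With chromosomes as units X did not stand apart (exact permutation p = 0.67, with 0.17 the smallest that 6 chromosomes allow). V was sparser still, and I and III, which were denser, also differed more from the other chromosomes than X did. X held 2 of the 100 best ranked combined peaks and 27 of the first 500, or 5.40% (95% Wilson interval 3.74 to 7.74), against 15.1% of the whole list. The replicates gave 2 of 100 each, and 25 and 40 of 500 nuclear peaks, against 14.3% and 15.9% of their first 9712. All 3 lists were below the share of their longer list at 500 peaks (exact binomial test, one-sided, adjusted p = 3.8e-07 or less over 9 tests). This test takes peaks as independent, although peaks cluster. It was added, with its direction, after the data were seen, and the tests within 1 list share peaks. In the best ranked 20% of the combined list X held 10.6% of peaks, and in the rest 16.3% (permutation of blocks, p = 0.0001, two-sided, the smallest possible). Among the nuclear peaks in the first 9712 of each replicate, the best ranked 20% and the rest gave 10.1% and 15.3% in replicate 1 and 11.9% and 16.9% in replicate 2, with the same p. The first 500 peaks of each list all had the highest score. So did the best ranked 20% of the combined list and of the first 9712 of replicate 1. These shares therefore rest on the order of the authors' peak numbers, whose meaning is not stated. By score alone, X held 12.62% of the combined peaks at the highest score and 16.54% of the others (permutation of blocks, p = 0.0002, two-sided), and 10.8% and 15.95% in replicate 2 (permutation p = 0.0001). In replicate 1 it held 14.1% and 13.6% (permutation p = 0.46), so the lower share was not seen there by score. The lsy-2 gene lies on X and unc-119 on chromosome III, and the extra copies of both in the strain were not examined separately.

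The replicates differed in their share of X peaks. X held 4105 peaks of replicate 1 (13.7%) and 4697 of replicate 2 (15.7%), a ratio of 1.14. Replicate 2 had more peaks in 17 of 17 X blocks of 1 Mb (exact sign test, adjusted p = 9.2e-05), a test that compares these libraries and not conditions. On IV, replicate 2 had fewer peaks, 4655 against 5026, with more in 4 of 17 blocks (exact sign test, adjusted p = 0.15). The ratios on I, II, III and V lay between 0.96 and 1.02, with an exact sign test adjusted p = 1 for each. The gap between the replicates on X was larger than on any other chromosome in peaks per Mb, but in both replicates X was sparser than the autosomes.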

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

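The test of whether mitochondrial peaks ranked too low was chosen after the result was seen, and that of the nuclear peaks of the same standing before.

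Peaks on mitochondrial DNA, which the chromosome comparisons leave out and the replicate overlap counts, were present in both replicate lists. Replicate 1 listed 21 of them and replicate 2 listed 17, while the combined list had 0. They covered 60.3% and 47.4% of the 13380 bp up to the last mitochondrial peak end, and the best stood at rank 1760 in replicate 1 and 1250 in replicate 2. No input values were analysed, so whether the enrichment exceeds that of total DNA was not examined here. Low rank is argued against as the reason for their absence from the combined list. Of each replicate, 14 mitochondrial peaks were among the first 9712 and overlapped such a peak of the other. The overlap itself carries little weight, since the peaks cover so much of this short sequence that many could overlap by chance. In that respect the nuclear peaks below are not a like comparison. Of nuclear peaks with the same standing, at least 98.1% were carried into the combined list, which is consistent with mitochondrial sequence having been left out when that list was made. Whether a filter did so, or the calling behind the combined list did not yield these peaks, stays open, and no biological explanation was tested.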

How the results depend on the processing

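The alternatives in the plan were fixed before the data were examined; ordering by peak number, merging overlapping peaks, rotating blocks, equal list lengths for the replicate comparisons, the X shares by rank and by highest score, the ratio of autosomes to X and the replicate differences per chromosome, with their sign tests on X and IV, were added after seeing the data. Of 65 alternative values, 48 kept their direction and their side of the threshold, or stayed within their interval. Not all of them were free to change. The best ranked 20% of the combined list tie in score, so ordering by peak number gave the same X shares. Replicate overlap counted as kept where it passed the threshold above the rotated lists, whatever its size. Replicate overlap ranged from 58.1% to 79.4% over its settings, each above the rotated lists. Spearman's rho of the replicate ranks moved from 0.74 to 0.59 in the better 50% of each list, 0.57 over every overlapping pair, 0.81 by peak number and 0.88 by peak number in the better 50%, and the cause was not tested. The shares of combined peaks found in replicate 1, replicate 2 and both moved from 98.9%, 99.7% and 98.6% to 98.3%, 99.2% and 97.47% when 50% of the shorter peak had to be shared. They were 99.5%, 99.8% and 99.3% in the better 50% of the combined list. They were 86.4%, 88.4% and 77.2% against the 9712 best ranked replicate peaks, where by construction fewer peaks can match. The X minus autosome density of -1.69 peaks per 100 kb ranged from -2.24 to -1.18 when a replicate was left out, and the arm minus centre density of -4.003 from -4.34 to -3.71. The X share in the better 50% of the combined list minus that in the rest was -2.08 percentage points (permutation p = 0.011), and ranged from -2.29 to -1.47 when a replicate was left out. Without replicate 2 it was -1.47 and missed the threshold (permutation p = 0.080). The X share in the best ranked 20% minus that in the rest was -5.65 points, and for peaks at the highest score minus the others it was -3.92 in the combined list, -5.19 in replicate 2 and 0.55 in replicate 1, where the direction was reversed (permutation p = 0.46). The X ratio of replicate 2 to replicate 1 fell from 1.14 to 1.07 among the first 3000 peaks by number and missed the threshold (exact sign test, adjusted p = 0.45), and the ratio on IV went from 0.93 to 1.06 (exact sign test, adjusted p = 0.45). No paired analysis was possible because the 3 lists used here hold peaks of the ChIP libraries, with no values of the input libraries to pair with them. The planned gene, gene type, base composition and transgene locus results were not run, as no annotation or sequence of WS220 was used here. The fixed list length of 30000 and the shared highest score limit what the lists can show of weak peaks and of the order of strong ones, and the unknown depth leaves differences between the libraries without a technical reference.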

Other observations

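The tests of whether the dense region came from 1 replicate, of extra copies and of weak X peaks, and the descriptions of spacing, were chosen after the result was seen.

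Combined regions lay close together. Across the 9276 merged regions the median distance to the next was 3.88 kb, against 7.20 kb for regions placed at random along each chromosome, and 32.6% of neighbours were under 2 kb apart, against 17.8% at random (permutation p = 0.001, one-sided, the smallest that 1000 draws can give). Placement at random ignores the uneven density along the chromosomes, so the test does not show close spacing beyond that unevenness. The 5 longest intervals without a combined peak were all on chromosome V. The longest ran from 16965985 to 17538589, 573 kb, and held 2 peaks of replicate 1 and 3 of replicate 2. The next, from 2698052 to 3194997, was 497 kb long.

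The densest 40 kb of the combined list was on chromosome III from 1919364 to 1958848, with 38 peaks, and 68.6 kb without a combined peak followed it. The next densest window, on chromosome V from 6212285 to 6250326, held 29, and in the better 50% of the list that window led with 21 against 19. One broad region called as several overlapping peaks is argued against, since 35 separate regions remained after merging and at most 27 in any window elsewhere. A broad region called as separate peaks stays open. Chance order of the spacings is argued against as well, because shuffling them within chromosomes gave at most 25 in 1000 draws. Shuffling also evens out regional density, and the chromosome V window with 27 regions passed 25 too. The test therefore shows clustering and nothing particular to this window. Its place as the densest window held in the list of replicate 1 and not in that of replicate 2. Windows of 40 kb there held up to 53 peaks of replicate 1 and 48 of replicate 2, while windows elsewhere reached 49 and 58. Whether replicate 1 gave the window its place in the combined list stays open. Extra copies of this locus in the strain remain open too, as 0 input libraries were analysed, and no biological explanation was tested.

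The higher number of X peaks in replicate 2 was tested further. A single X locus is argued against because no 1 Mb block held more than 12.7% of the excess. Weak peaks at the end of the lists stay open as a part of the reason. The excess was not confined to the peaks after the first 9712. Among the first 3000 peaks the ratio was 1.15 by score (adjusted exact sign test p = 0.025 over 1 Mb blocks, higher in 14 of 17 blocks) but 1.07 by peak number (adjusted exact sign test p = 0.45, higher in 10 of 17). Among the first 9712 the ratio was 1.11 in both orders, with replicate 2 higher in 14 of 17 blocks. The adjusted exact sign test p was 0.0059 by score and 0.025 by peak number. Library depth and a difference between the animals of the replicates stay open, and no biological explanation was tested.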
